A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

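Total RNA of a Halobacterium salinarum NRC-1 strain with knockouts of ura3 and gap was hybridised to 2-colour spotted arrays against a common NRC-1 reference RNA, per the labels. The 4 samples stand for 4 conditions, high or low oxygen in light or dark, with 1 sample per condition. Each sample was hybridised on 2 arrays of opposite dye orientation, which gave 8 arrays. Replicate 1 of every condition has the sample in Alexa 532 and replicate 2 in Alexa 647, so dye orientation and series of slides cannot be separated, but each series holds all 4 conditions. The arrays of a sample are technical replicates of the same extract and were averaged before any test.

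Per the file headers, the scanner files hold the mean spot intensity, the median background intensity and the background standard deviation per dye at a high and a low gain, on a linear scale and without background subtraction. A spot confidence in percent is also given per the file headers, and in these files it falls below its top value only where a pixel is saturated. The value table deposited with the series holds log10 ratios: in 81.6% to 96.8% of the spots of an array, the values lie within 0.01 of log10 of Alexa 532 over Alexa 647 high-gain intensity plus 1 constant per array. Its direction is therefore Alexa 532 over Alexa 647 on all arrays, while the reason for the constants stays unknown. The column medians of that table, on the log10 scale, are 0.0447 and 0.134 for replicates 1 and 2 in high oxygen and light, 0.0253 and 0.125 in high oxygen and dark, 0.0650 and 0.0446 in low oxygen and light, and 0.0311 and 0.164 in low oxygen and dark. The image software and the authors' filters are not stated.

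Each array has 10752 spots, which form 2688 probe sets of 4 spots. The platform annotation names 1 gene for 133 of the probe sets and none for the other 2555, which are unnamed here, not without a gene. No probe has several symbols. By gene ID, 0 of the 133 genes matched the RefSeq table, which belongs to another assembly, so symbols are those of the platform. Unnamed probes are written as P with the position of their first spot.

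With limma 3.58.1 in R 4.3.3, high-gain intensities were corrected by normexp with offset 50 and normalised by loess within each array, with no scaling between arrays. Ratios were turned to sample over reference by the dyes in the labels. Intensities of single channels, and the bounds drawn from them, were in addition quantile-scaled between arrays on mean log2 intensity. The spots of a probe set were averaged on the log2 scale, and probe sets with at least 1 spot left on every array were tested. That kept 2593 probe sets, 131 of them named, and left out 95, among them those of purB and gyrB. Control spots are not identified in the files, so none were left out as controls. Saturated spots were kept.

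The design, the alternatives, the gene lists and the rule for named genes were written before the data were examined. The design leaves out spots with an outlier mark, but the scanner files hold no such mark. Spots without a value in the authors' table were taken in its place: 645 on each array with the sample in Alexa 532 and 594 on each with the sample in Alexa 647. That reading was settled after the files, and counts under several settings, had been seen. With those spots kept, the counts of changed probes are 0 for oxygen, 0 for light and 490 against the reference, in place of 14, 0 and 748. Also chosen after the data were seen were the named genes as the set that gene lists are compared with, the correlation across probes as the summary of the interaction, the filter to well-measured probes, and the use of the rule for named genes on named probes alone.

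The 4 values per probe, 1 per sample, were fitted with lmFit and eBayes with centred terms for oxygen (low minus high) and light (light minus dark), and the intercept is the mean of the 4 samples against the reference. The fit has 1 residual degree of freedom, pooled across probes to 11.2. Adjusted p-values are Benjamini-Hochberg values, with 0.05 as the threshold. The reference is a single RNA, so the test against it leaves out the reference's own spread. As the arrays of a sample were averaged, a gap between dye orientations shared by all samples enters no standard error or p-value here. Lists with at least 3 measured members, 11 in all, were tested with camera at a preset inter-gene correlation of 0.01. They were tested again with an estimated correlation and with fry. With an estimated correlation camera uses the 1 residual degree of freedom, so hardly any list could pass it here. For the TCA cycle and oxygen its unadjusted p rose from 0.486 to 0.605, although the estimated correlation was -0.2. A call lost that way therefore says little about correlation between genes. The oxygen by light interaction uses up the residual and has no test. It is given as the difference of the oxygen effects in light and in dark, with the half-difference of the dye orientations as technical error.

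The rule named the targeted genes, up to 10 genes per direction with the largest log2 value among those past the test with 1 sign in both contrasts (for the reference, in all 4 samples), filled by the largest moderated t, then 2 to 4 members of each list, and 5 genes per direction for the interaction. A probe was counted as above background on an array where its mean intensity exceeded the local background by 2 background standard deviations. Well-measured probes, 754 of those tested and 64 of them named, were above background in all 4 samples on at least 1 array each and in the reference on at least 1 array. The number of arrays, and on them the signal over background, limits the precision.

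The method was tested on simulated data: in 100 draws of 2593 probes with 200 changed, limma called 93.9% of oxygen changes of log2 size 1 and 100% of those of size 2. On average 6.85% of the calls were false, up to 17.8% in 1 draw. The simulated noise was independent between probes, with spreads drawn from limma's own fit to these data. It held no dye bias, background floor or shift of a print block. These shares therefore do not show how often changes are found on the real arrays. In 27 of the 100 draws limma gave every probe the same spread, since 1 residual degree of freedom leaves that estimate poorly determined.

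Alternatives were no background correction, plain subtraction, median centring, print-tip loess, scaling between arrays, a filter on dim probes, other uses of spots, the authors' table, each dye orientation alone, the 8 arrays as separate values or with the sample as a block, each array and each sample left out, other variance moderation, other covariates and a looser threshold of 0.1. Added after seeing the data were the well-measured probes alone, saturated spots at their low-gain value, probes with an empty spot left out, lists compared with all probes, lists of the well-measured probes or of the Alexa 532 arrays with an estimated correlation, and the interaction over all probes.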

Results

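The series measured RNA levels in Halobacterium salinarum NRC-1, an archaeon of saturated brines that can live from respiration, arginine fermentation or light. The strain carries knockouts of ura3, a gene of pyrimidine synthesis, and of gap, the gene of glyceraldehyde-3-phosphate dehydrogenase. Cultures of 50 mL in 125 mL flasks grew in rich medium to mid-log phase, either with high oxygen (shaken at 210 rpm) or with low oxygen (100 rpm in a stoppered flask), each in light or in dark. The reference was mid-log NRC-1 RNA from cultures at an OD600 of 0.5 to 0.6. Each of the 4 conditions has 1 sample on 2 dye-flip arrays, so oxygen and light are each compared over 2 samples against 2, and no condition has replicate cultures. On the arrays with the sample in Alexa 532, the sample rose above background at 161 to 251 of the 2688 probe sets, with a median background of 6545 to 11205 intensity units. With the sample in Alexa 647 it did so at 778 to 1581 probe sets, with a median background of 1084 to 4122.

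The targeted gene ura3 is present on the array as pyrF, orotidine 5'-phosphate decarboxylase. Its probe was above background in neither channel on any of the 8 arrays, and its log2 ratios to the reference were 0.02 in high oxygen and light, -0.73 in high oxygen and dark, -0.26 in low oxygen and light and -0.34 in low oxygen and dark. At that level, pyrF checks none of the labels. No probe is named gap.

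The first comparison asks which genes answer to oxygen. The folate synthesis gene folP was the only named gene to pass the test: its ratio to the reference was higher in low oxygen by a log2 of 0.95 (SE 0.18, n = 2 samples per oxygen level), by 0.97 in light and 0.92 in dark. Its sample channel alone, scaled between arrays, was not higher, with a mean log2 intensity of 11.84 in low and 11.97 in high oxygen. Its reference channel was above background on no array. Of the chemotaxis transducers, htr8 had an oxygen value of -0.87 (SE 0.18), with log2 ratios that were lower in low oxygen on all arrays, and htr4 one of 0.65 (SE 0.18). Genes of central metabolism that did not pass had values above 0 for hemL of haem synthesis (0.74), purE of purine synthesis (0.57), lpdA, dihydrolipoamide dehydrogenase (0.53), and arcC, the carbamate kinase of arginine fermentation (0.43). Values below 0 belonged to rpmC, ribosomal protein L29 (-0.62), moaA (-0.52) and the translocation channel gene secY (-0.45). Also below 0 were guaB, IMP dehydrogenase (-0.38), and gdhA1, a glutamate dehydrogenase (-0.37). Of all these genes, only purE, lpdA, arcC, secY and guaB are well measured. The sample channel of htr8, htr4, hemL, rpmC and gdhA1 was above background on 3 arrays and that of moaA on 2. For htr4 and moaA the reference channel was above background on no array.

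In limma's test, 14 of 2593 probes changed with oxygen, 12 higher and 2 lower in low oxygen, and 425 had an unadjusted p under 0.05 where chance gives about 130. For folP the adjusted p was 0.0424, and its value was 0.26 without background correction and 0.07 (SE 0.13) with print-tip loess, neither past the test. Its sample channel was above background on 3 of the 8 arrays. Over the named genes, 1 passed against all probes and 2 when adjusted over the list alone, folP and htr8 (limma adjusted p of 0.0321, and 0.0638 over all probes). Of the 14 probes, 3 are well measured, among them the unnamed P365 with 1.40 and P3831 with 0.98. The 2 lower probes are P2361 with -1.34 and P627 with -0.94, each above background in the sample channel on 2 arrays and in the reference channel on none.

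Among the lists, all 5 pyrimidine synthesis genes had oxygen values above 0, such as pyrI (0.40) and carB (0.35). Without background correction and on the Alexa 647 arrays 3 of 5 did, and 0 passed. Among the 5 is the targeted pyrF (0.05), with its probe at background level, at 0.64 on the Alexa 532 and -0.53 on the Alexa 647 arrays. Of the 5 genes, 2 are well measured. The sample channels of carA and carB were above background on 1 array each and their reference channels on no array. All 5 genes of the other retinal proteins list also had values above 0, with hop, halorhodopsin, at 0.49, sop1 at 0.27 and sop2 at 0.11. Among them are the transducer genes htr1 (0.29) and htr2, which also belong to the motility and chemotaxis list. The list's median stayed above 0 under every normalisation and in both dye orientations (4 or 5 of 5 genes). With scaling between arrays, in the authors' table and on the Alexa 647 arrays, 3 of 5 genes lay above the median of all probes. The median of amino acid synthesis also stayed above 0 under these settings (8 of 10 genes above 0, with hisA 0.53 and hisB 0.38). Without background correction, with print-tip loess (median 0.03) and on the Alexa 532 arrays, 6 of 10 of its genes lay above 0. The reference channel of hisA was above background on no array. The medians of the TCA cycle (5 of 6, with mdh 0.29, icd 0.20 and citZ 0.14) and purine synthesis (4 of 6, with purF 0.40 and purL 0.22) were above 0 as well. In the authors' table these 2 medians were 0.04 and 0.05, under the 0.09 of all probes (1 of 6 and 2 of 6 genes above that). With print-tip loess 3 of 6 TCA cycle genes lay above 0. All 4 DNA repair genes lay below 0, uvrA at -0.18 and uvrB at -0.08, but 2 of 4 did in the authors' table, with a median of 0.07 there. The 11 motility and chemotaxis genes split 7 to 4, with htr6 at 0.40; 0 passed over all probes and 2, htr8 and htr4, when adjusted over the list alone. The aminoacyl-tRNA synthetases split 7 to 5 (serS 0.33, proS 0.32, aspS -0.29) and the cobalamin synthesis genes 2 to 2 (cbiT -0.27, cbiQ 0.14). Of the 4 chaperone and proteasome genes dnaK had the largest value, 0.31, and of the 3 glycolysis genes eno was at -0.34 and ppsA, partly saturated, at 0.30.

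With camera, 0 of the 11 lists passed for oxygen (0 at an unadjusted p under 0.05, lowest adjusted p 0.746), 0 with an estimated correlation (lowest adjusted p 0.974), and 0 with fry. camera compares with the other named genes, and its direction was down for the motility list (median 0.01, mean 0.03) and the aminoacyl-tRNA synthetases (median 0.07, mean 0.04) although their values lay above 0. For the chaperone list median (-0.02) and mean (0.05) differed in sign, as they did for cobalamin synthesis (0.003 and -0.03). Lists too small to test had bat at -0.01, mvk at -0.02, nuoL at -0.01, glpK at -0.21, msrA at -0.27, phoU at 0.28, hemA at -0.07, rpl12p at -0.23, orc7 at -0.13 and orc8 at -0.13, and 0 of their members passed. No named probe belongs to the lists for gas vesicles, DMSO respiration, terminal oxidases, ATP synthase, RNA polymerase, general transcription factors, metal and potassium uptake or the plasmids.

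The oxygen count depended on the arrays and on the probes used: it was 0 on the arrays with the sample in Alexa 532 alone, 112 on those with Alexa 647 alone, 126 with the sample as a block and a dye term, 0 with the 8 arrays as separate values and a dye term, and 0 without any 1 of the 8 arrays. With the well-measured probes alone, a filter chosen after the values were seen under which limma took the same spread for every probe, 134 of 754 passed (93 higher and 41 lower in low oxygen). There, purE (1.48-fold), lpdA (1.44-fold), arcC (1.35-fold), glyA (1.33-fold), htr6 (1.32-fold), pyrI (1.32-fold) and glnA, glutamine synthetase (1.30-fold), rose in low oxygen, and secY (log2 of -0.45) and guaB (-0.38) fell, each with an SE of 0.14. On the Alexa 647 arrays in dark glnA went the other way, at -0.38 in low and -0.19 in high oxygen. In the other pairs of arrays it was higher in low oxygen.

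**Figure D1:**
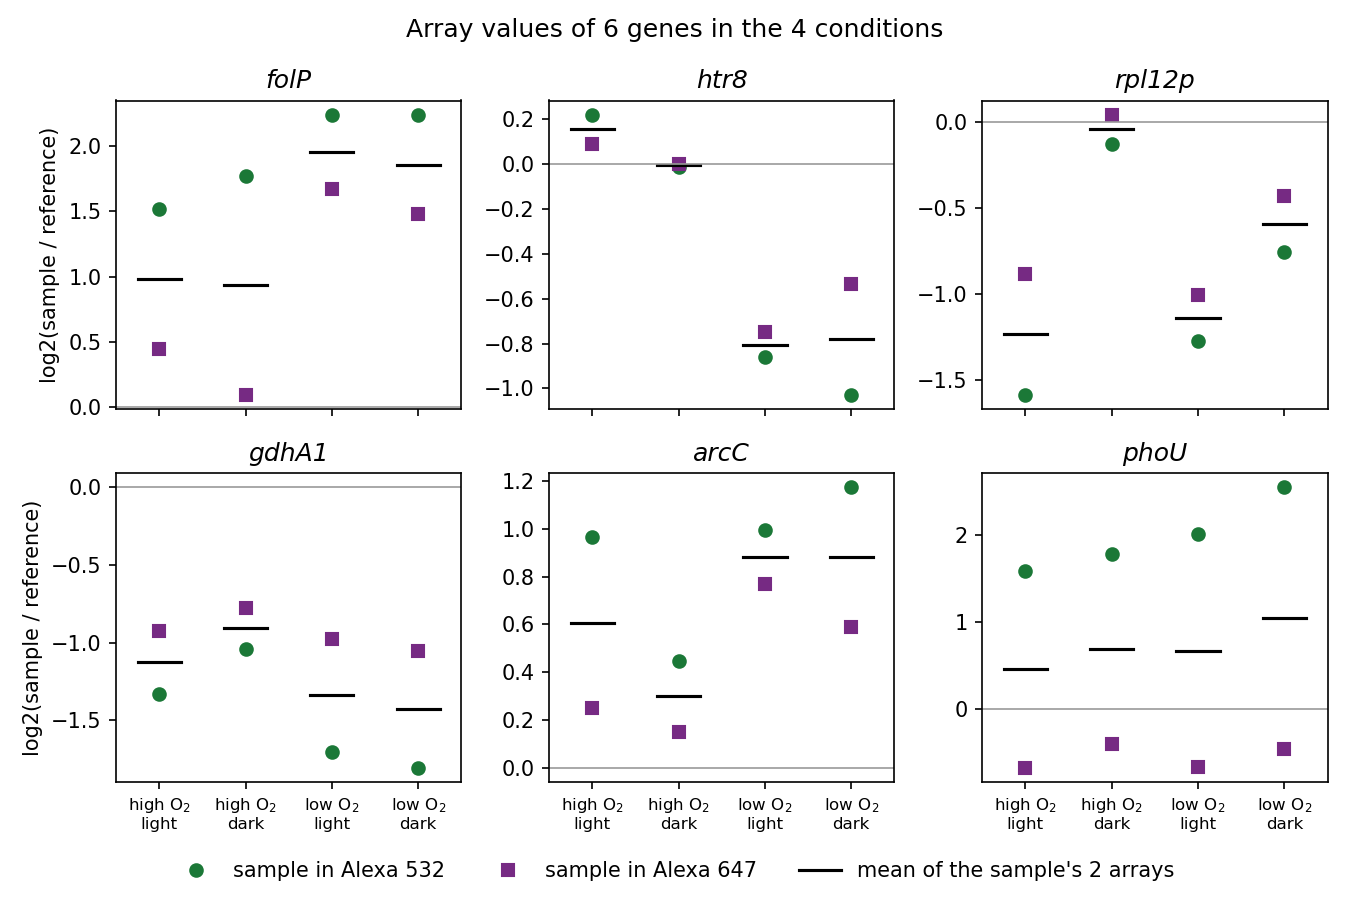
Log2 ratio of sample over reference (vertical axis) on each of the 8 arrays for 6 genes in the 4 conditions (horizontal axis), with circles for the sample in Alexa 532, squares for Alexa 647 and a bar for the mean of the 2 arrays of a sample. The ratios of folP are higher and those of htr8 lower in low oxygen, the ratio of rpl12p is lower in light, and the 2 orientations of phoU lie on opposite sides of 0.

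The second comparison asks which genes answer to light. The ribosomal protein gene rpl12p had the largest light value of the named genes, -0.87 (SE 0.20), with log2 ratios of -1.23 and -1.14 in the 2 light samples against -0.05 and -0.60 in the 2 dark samples, and no probe, named or not, passed the test. The next values below 0 were those of rpmC, the other ribosomal protein gene with a name (-0.54), and the glycolysis gene eno, enolase (-0.45). Values above 0 belonged to serB, phosphoserine phosphatase (0.47), the transducer htr6 (0.37), bat, activator of the bacteriorhodopsin genes (0.37), msrA, methionine sulfoxide reductase (0.35), and serS (0.29). The genes phoU (-0.30), guaB (-0.30), cbiG (-0.28) and sucC (-0.27) had small values below 0. The values of mch, pyrF, thiL, gdhA2 and trpB come from probes above background on no array. For bat the sample channel was above background on 2 arrays and the reference channel on no array.

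In limma's test, 0 of 2593 probes changed with light, and 198 had an unadjusted p under 0.05 where chance gives about 130; 7 of these are named. The lowest adjusted p was 0.208, and that of rpl12p was 0.635 (0.159 when adjusted over the list alone, with the named genes as the list). Over the named genes, 0 passed against all probes and 0 when adjusted over the list alone.

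Of the 11 motility and chemotaxis genes, 9 had light values above 0 (median 0.19), among them htr6, htr4 (0.30), cheB (0.24) and htr1 (0.22), and 0 passed. The list had an unadjusted p of 0.0136 with camera and an adjusted p of 0.150, or adjusted p = 0.852 with an estimated correlation. Its median was above 0 under every normalisation and in both dye orientations, with 8 to 11 of 11 genes above 0, but on the Alexa 647 arrays alone it was 0.06 against 0.07 for all probes, with 5 of 11 genes above that. The transducer gene htr2 (0.21), hop (0.04) and sop1 (-0.02), all of the other retinal proteins list, were not past the test either. Of 6 TCA cycle genes 5 lay below 0 (sucC, citZ -0.21, sucD -0.16), but 2 of 6 did in the authors' table, where all 6 were under the median of all probes, 0.16. The other lists went both ways or turned their median's sign under an alternative: cobalamin synthesis (cbiT -0.30, cobN 0.21), amino acid synthesis (hisB 0.37, hisD -0.19), the aminoacyl-tRNA synthetases (proS -0.14), chaperones and proteasome (dnaJ -0.13), glycolysis (tpiA -0.13), purine (purM 0.30, purE 0.19) and pyrimidine synthesis (carB -0.17) and DNA repair (mutL 0.18). Some values given for these lists come from dim probes. The probe of mutL was above background on no array. For htr4, carB and tpiA the reference channel was above background on no array. Smaller lists gave arcA 0.25, arcC 0.16 and nuoL 0.13, and 0 of their members passed.

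With camera, 0 of the 11 lists passed for light (1 at an unadjusted p under 0.05), 0 with an estimated correlation and 0 with fry, while fry's test for change in either direction gave the motility list an adjusted p of 0.0384. For the aminoacyl-tRNA synthetases the median (-0.004) and the mean (0.01) differ in sign. The motility list passed on the arrays with the sample in Alexa 532 alone (camera adjusted p of 0.0255, but adjusted p = 0.948 with an estimated correlation) and with the well-measured probes alone (0.0291, 7 members, but adjusted p = 0.969 with an estimated correlation), within a range of 0.0255 to 0.969 over the 18 alternatives. With the well-measured probes alone, 46 probes passed limma's test, 16 higher and 30 lower in light, with rpl12p (log2 of -0.87, SE 0.14) and eno (-0.45) lower and serB (0.47) higher. Within either dye orientation and with the sample as a block 0 passed, and with median centring 8 did, rpl12p among them.

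The third comparison sets the mean of the 4 knockout samples against the NRC-1 reference, which differs in strain and in culture at once. The glutamate dehydrogenase gene gdhA1 was the lowest named gene, with a log2 of -1.20 (SE 0.09, n = 4 samples), and it was below the reference in all 4 samples and both dye orientations. The ribosomal protein genes rpmC (-0.78) and rpl12p (-0.75) fell as well, as did panB of pantothenate synthesis (-0.74), speB, agmatinase (-0.62), cbiT of cobalamin synthesis (-0.53) and cmk, cytidylate kinase (-0.52). Higher than in the reference was arcC, by 1.59-fold (log2 of 0.67, SE 0.09). The direction held in both dye orientations for each of these genes. Of them, gdhA1, rpmC and panB are not well measured. Their sample channel was above background on 3 arrays each, and their reference channel on 6, 6 and 5. In the high oxygen dark sample, rpl12p was at -0.13 on the Alexa 532 and 0.04 on the Alexa 647 array, and rpmC at 0.20 and -0.47. In the other samples both genes were below the reference on every array. folP passed the test with a log2 of 1.43, but its reference channel was above background on no array, and with that channel raised to the lowest level measured above background the value is -0.17, so no rise over the reference is shown. The same holds for the phenylalanyl-tRNA synthetase gene pheS (-0.73), whose sample was above background on 3 arrays and reference on none, so no fall is shown.

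In limma's test, 748 of 2593 probes differed from the reference, 312 higher and 436 lower, and 1041 had an unadjusted p under 0.05. Of the 748, 645 had 1 sign in all 4 samples, 575 had the same sign in both dye orientations, 218 were well measured and 233 were above background in neither RNA. Of the 131 named genes, 38 passed, 6 higher and 32 lower, and also 38 when adjusted over the list alone; 29 had 1 sign in both orientations and 19 were well measured. The adjusted p was 4.71e-06 for gdhA1, 0.000144 for rpmC, 0.000353 for rpl12p and 0.000409 for arcC.

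By list, 3 of 6 TCA cycle genes fell (citZ -0.59, sucC -0.29, sucD -0.27), also 3 when adjusted over the list alone, and all 6 lay below 0, though 3 of 6 did on the Alexa 647 arrays. Of 12 aminoacyl-tRNA synthetases 4 passed with values below 0 (serS -0.32, lysS -0.31, ileS -0.26 and pheS), also 4 when adjusted over the list alone. Of 10 amino acid synthesis genes 4 passed, trpC (0.51), with a probe above background on no array, and argH (-0.32), hisG (-0.32) and aroC (-0.28); 6 passed when adjusted over the list alone. On the Alexa 647 arrays alone the last 3 were at 0.0045, 0.051 and 0.14, so their direction rests on the Alexa 532 arrays. In cobalamin synthesis 2 of 4 fell (cbiT, and cbiG with -0.27, from -0.50 on the Alexa 532 and -0.05 on the Alexa 647 arrays), in purine synthesis purF (-0.48), in glycolysis eno (-0.33), in DNA repair uvrB (-0.39, from -0.97 on the Alexa 532 and 0.18 on the Alexa 647 arrays). The sample channel of purF was above background on 2 arrays and its reference channel on 1. In isoprenoid synthesis mvk (-0.34) passed, and in pyrimidine synthesis pyrF (-0.33), with its probe at background level. Of 11 motility and chemotaxis genes, htr18 (0.30) and htr8 (-0.36) passed; htr8 was at 0.15 and -0.01 in the 2 high oxygen samples and at -0.81 and -0.78 in the 2 low oxygen samples, so its value below the reference comes from the latter 2. For htr18, mvk and aroC the reference was above background on no array, and the sample on 3, 2 and 3, so neither the size nor the direction of their differences is shown. No gene of the other retinal proteins list passed (hop 0.20, htr1 0.17, htr2 -0.12, sop2 0.09). Nor did any chaperone or proteasome gene (psmB -0.13, dnaJ -0.11, dnaK -0.11, psmA -0.09). The same holds for bat (0.12), nuoL (0.02), glpK (-0.16), msrA (0.08), hemA (-0.18), hemL (-0.09), orc7 (-0.17) and orc8 (0.07).

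The phosphate regulator phoU rose by a log2 of 0.72 in the mean, yet its value was 1.98 with the sample in Alexa 532 and -0.54 in Alexa 647, so its direction rests on the first orientation. For citZ the values were -1.28 and 0.09. With print-tip loess, folP was at 0.23, pheS at -0.17, cbiT at -0.32, cbiG at -0.17, purF at -0.0044, htr8 at -0.02 and serS at -0.02, which ended their calls. Among the remaining named genes past the test, gatC (0.45) and truA (-0.51) have probes above background on no array. Genes above 0 that did not pass include carB (0.23), menD (0.21), cheY (0.19) and tmk (0.18). The unnamed probe P4433 was the lowest of all, at -2.19, with array values from -2.62 to -1.70; its sample channel was above background on 2 of 8 arrays and its reference channel on 7.

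With camera, 0 of the 11 lists passed against the reference (1 at an unadjusted p under 0.05, motility and chemotaxis with p = 0.0391), 0 with an estimated correlation (lowest adjusted p 0.976) and 0 with fry; fry's test for change in either direction gave pyrimidine synthesis an adjusted p of 0.0113. camera's direction was up for pyrimidine synthesis (median -0.12, mean -0.06) and amino acid synthesis (median -0.15, mean -0.09), since the other named genes lay lower. The reference count was 0 with plain background subtraction, 388 with print-tip loess, 1200 and 1494 on the arrays with the sample in Alexa 532 and Alexa 647 alone, 986 with the sample as a block, and 0 to 47 without any 1 array. With the well-measured probes alone, 357 passed, and so did the motility list, upward (camera adjusted p of 0.0356, or adjusted p = 0.968 with an estimated correlation; range 0.0356 to 0.976 over the 18 alternatives).

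**Figure D2:**
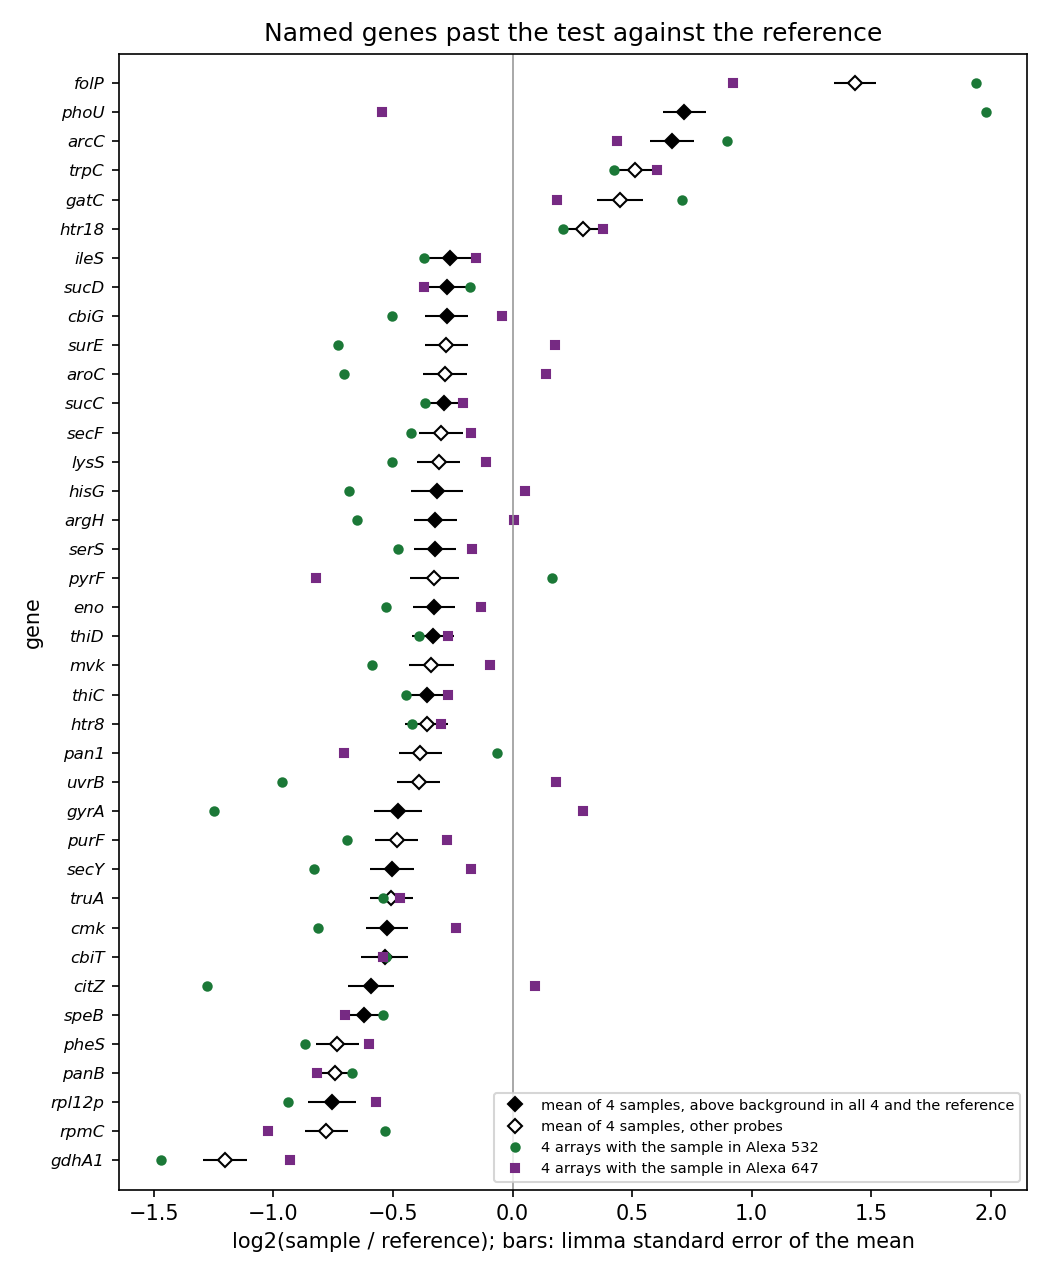
Log2 ratio of sample over reference (horizontal axis) for the 38 named genes that passed limma's test against the reference (vertical axis), with diamonds for the mean of the 4 samples, filled where the probe is well measured, bars for the standard error, and circles and squares for the 4 arrays of each dye orientation. The 6 higher genes range up to 1.43 and the 32 lower ones down to -1.20, and 29 of the 38 have both orientations on 1 side of 0.

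The last comparison asks whether the oxygen effect depends on light; with 1 sample per condition it has no test. Across the 754 well-measured probes, the oxygen effects in light and in dark correlated with r = 0.625 (across probes, which are not independent replicates). Within the Alexa 532 arrays r was 0.417, and within the Alexa 647 arrays 0.626. The largest positive differences, light minus dark, were those of purD (0.95), the tRNA synthetase genes aspS (0.92), hisS (0.88) and proS (0.67), and bat (0.71). The largest negative ones were those of hisG (-0.82), mch (-0.80), trpC (-0.75), trpB (-0.69) and nadA (-0.69). The half-difference of the dye orientations, the technical error, went from 0.07 (hisS) to 0.69 (hisG). Of these 10 genes, proS and hisG are well measured, and mch, trpC, trpB and nadA were above background in the sample channel on no array.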

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

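The search for opposed oxygen effects, in the form used here, was chosen after the data were seen, and the difference between light and dark was not tested for any gene. A gene is listed where its oxygen effect had 1 sign in light and the opposite sign in dark in both dye orientations. Among the 93 genes named in the text this held for 8, and among all 131 named genes tested for 11. Both are smaller shares than the 12.5% that independent signs alone give, so the list shows no excess of such genes. Of the 8, purD, aspS, trpC and nadA had also been picked for a large difference between light and dark. No gene was compared for a sample far from the others, since each condition has 1 sample.

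The purine synthesis gene purD had an oxygen effect of 0.63 in light and -0.32 in dark, a difference of 0.95. For aspS the effects were 0.17 and -0.75, a difference of 0.92. For the sensory rhodopsin gene sop2 they were 0.39 and -0.18, a difference of 0.58. For dnaJ they were 0.13 and -0.29, a difference of 0.41, and for the proteasome gene psmB 0.15 and -0.22, a difference of 0.37. For nuoL both effects were small, 0.03 and -0.05, with a difference of 0.078. The opposite order was seen for trpC, with -0.20 in light and 0.56 in dark (difference -0.75), and for nadA, with -0.60 and 0.09 (difference -0.69). Of the 8 genes, 2 are well measured, psmB and nuoL, and the sample channel of trpC and nadA was above background on no array.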

How the results depend on the processing

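The settings with well-measured probes, low-gain values, empty-spot probes left out, lists against all probes, lists of well-measured probes or of the Alexa 532 arrays with an estimated correlation, and the interaction over all probes were added after seeing the data. The count of 14 oxygen probes became 9 (5 higher, 4 lower) without background correction, 0 with plain subtraction, 65 (37 and 28) with median centring, 0 with print-tip loess, 5 with scaling between arrays, 25 without the dimmest probes, 0 with empty spots kept, 0 with the median of spots, 0 on the Alexa 532 and 112 on the Alexa 647 arrays alone, 0 with 8 separate arrays, 126 with the sample as a block, 8 with trend and robust moderation, 32 at an adjusted p under 0.1, 7 without light in the model, 134 with well-measured probes, 5 with low-gain values, 2 without empty-spot probes, and 0 without any 1 array. Of the 14 probes, 12 kept their call and direction on the Alexa 647 arrays, and the authors' table gave 10 calls, 4 of them shared. All 14 were also called with the block, where direction could not turn because the effects are those of the main fit. The block fit takes its spread partly from the dye flips of the same extracts, so its calls do not count as replication. The count of 0 for light became 8 with median centring and 46 with well-measured probes (0 without any 1 array). The count of 748 against the reference became 0 with plain subtraction, 388 with print-tip loess, 490 with empty spots kept, 1200 and 1494 on the Alexa 532 and 647 arrays alone, 493 with the intercept only, 357 with well-measured probes, and 0 to 47 without 1 array. Without 1 array the dye bias of 1 sample no longer cancels, and the prior degrees of freedom fell to between 2.09 and 4.27. Which of these lowered the count was not tested. Without background correction 391 probes were higher and 351 lower than the reference, and the authors' table gave 53 and 773, beside 312 and 436; this table moves the median of all probes by -0.15 against the reference and by 0.16 for light, and plain subtraction by -0.13 against the reference. The count of 0 lists became 1 for light on the Alexa 532 arrays and 1 with well-measured probes, and 1 against the reference with well-measured probes (0 without any 1 array in each comparison). With an estimated correlation each of these, the motility list, lost its call (adjusted p = 0.948 and 0.969 for light, 0.968 for the reference). That form of camera rests on 1 residual degree of freedom, so the loss does not show that correlation between genes gave the calls. The interaction's r of 0.625 became 0.417 on the Alexa 532 arrays and 0.352 over all probes.

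Against the reference, direction turned for phoU with plain subtraction (-0.37), print-tip loess (-0.0043) and the Alexa 647 arrays (-0.54); on those arrays also for citZ (0.093), glpK (0.45), uvrB (0.18), hemL (0.61), argH (0.0045), hisG (0.051) and aroC (0.14); without background correction for mvk (0.011), hisG (0.00904) and aroC (0.040); in the authors' table for trpC (-0.073), gatC (-0.10) and tmk (-0.29); and for pyrF with print-tip loess (0.021) and on the Alexa 532 arrays (0.17). Of the other values of named genes past the test there, 520 kept direction and call and 352 lost the call. For folP and oxygen, 8 kept it and 19 lost it, with 0 turned. Fewer arrays or probes set some of these counts; otherwise the cause was not tested. No paired analysis was possible because replicate numbers mark dye orientation, which the fits with a dye term hold. Plain subtraction leaves no value for most probes with a channel under its background, and signal over background limits all results: the sample channel was above background at 161 to 251 probe sets on the Alexa 532 arrays.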

Other observations

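The filter to well-measured probes and the tests of the 3 patterns weighed here were chosen after the patterns, and values close to those the tests measure, had been seen; leaving out each array and print-tip loess were planned.

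With the well-measured probes alone, 5 of the 7 motility and chemotaxis genes left were higher than the reference in the mean of the 4 samples: cheY by 1.14-fold, htr6 by 1.14-fold, cheA by 1.13-fold, cheR by 1.13-fold and htr1 by 1.12-fold, each with a standard error of 0.07 on the log2 scale. In the high oxygen dark sample htr6 (-0.27) and htr1 (-0.14) were below the reference. By dye orientation, cheR was at 0.36 on the Alexa 532 and -0.01 on the Alexa 647 arrays, cheY at 0.36 and 0.02, and htr6 at -0.06 and 0.43, so each of these 3 rests on 1 orientation. The other 2, cheB (log2 of 0.10) and htr2 (-0.12), did not pass, and the list of 7 had a camera adjusted p of 0.0356, or adjusted p = 0.968 with an estimated correlation. In the authors' table the median of the 11 motility and chemotaxis genes was -0.04, above that of all probes there, -0.14. These changes are small next to the fall of rpl12p (log2 of -0.75) and speB (-0.62) under the same filter. Of the 64 named genes tested there, 29 differed from the reference, 7 higher and 22 lower, 9 changed with oxygen and 3 with light.

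Of the 14 probes that changed with oxygen, 5, folP among them, have a spot that the authors' table leaves empty, and all 5 lie in 1 print block. A blemish in one place would leave the copies of these probes in the other part of the array near 0. Those copies had a mean oxygen effect of 0.86 (SD 0.35) on the Alexa 647 arrays, against 2.55 (SD 0.55) for the first copies. The 5 probes were called on the mean of all their copies, so both parts were selected to be high. This comparison, made on the Alexa 647 arrays alone, therefore cannot exclude a blemish that raised the first copies. A shift of the whole block may contribute: the other 85 tested probes of that block had a median oxygen effect of 0.29, against 0.04 for all other probes, a value between the bounds set for and against it. With print-tip loess, which removes such a shift, folP went from 0.95 (SE 0.18) to 0.07 (SE 0.13), so the smaller value alone ended its call, and the other 4 went from values of 1.05 to 1.31 to values of 0.48 to 0.83 and lost theirs, with prior degrees of freedom that fell from 10.2 to 3.39. An effect of oxygen on those 4 stays open beside the block.

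Arrays of opposite dye orientation opposed each other over all probes, with r from -0.68 to -0.49, while arrays of the same orientation had r from 0.76 to 0.90. Had the dyes been exchanged in the labels of 1 orientation, the oxygen effects of the 2 orientations would oppose each other too. Instead, across the well-measured probes they correlated with r = 0.520, and the light effects with r = 0.586. Over all 2593 tested probes these correlations were 0.094 and 0.033, and in the second of 4 intensity classes -0.148 and -0.130. The 2 orientations therefore shared these effects in the well-measured probes, but hardly over all probes. The mean ratios of the orientations correlated with r = -0.281 in the dimmest of 4 intensity classes, -0.845 in the second, -0.432 in the third and 0.177 in the brightest. A dye or background bias of single probes that outweighs the ratio below the brightest class could give such values. The opposition did not grow steadily toward dim probes, and its weaker value in the dimmest class was not explained. No biological explanation was tested, since both arrays of a pair hold the same extracts.

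The lower rpl12p ratio in light did not pass limma's test over all probes (adjusted p of 0.635, and 2.63e-07 to 0.998 over the alternatives). Saturated spots cannot account for it, since at their low-gain value the light effect was -0.93 against -0.87 as measured. No 1 array decides it: over the 8 arrays left out in turn it stayed between -1.04 and -0.69. Nor do probes of like brightness share it, as the 100 nearest in intensity had a median light effect of 0.0049 and 0 of them lay below rpl12p. It may reflect a lower rpl12p transcript level in light, a hypothesis found and tested on the same 4 samples, and a difference between single cultures stays open.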
